A study of Anolis carolinensis with 2 samples.

How the data were processed

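RNA was sequenced from 2 whole embryos of the green anole, Anolis carolinensis, a lizard. One embryo had 28 somite pairs and the other had 38. Per the labels' protocols, total RNA was isolated and libraries were made with the NuGEN Ovation RNA-Seq kit. Per the series description, untrimmed reads were aligned with TopHat to the AnoCar2.0 assembly. Cufflinks is named in the submitters' processing notes, and the versions of both tools are not given in the sources used here. There was 1 library per stage, so embryo, library and stage cannot be separated, and no p-value was computed.

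The deposited values are FPKM, fragments per kilobase of effective transcript length scaled to the mapped fragments, per the file headers. Each library had a table of 21085 genes and a table of 22232 transcripts, with the same identifiers in both libraries. Per the file headers, the transcript tables also held each transcript's fraction of its locus and its coverage signal, which entered no comparison. The deposited interval of a gene's FPKM equalled the FPKM plus or minus 2 times its square root, not below 0, for 99.5% of genes in each library. These bounds therefore carry no information on depth or transcript length. Every gene had the status OK. Of the annotated transcripts, 86.1% had a length divisible by 3, so most lengths here are coding lengths.

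Fragment numbers were recovered from the FPKM values. The product of FPKM and effective length fell on whole multiples of 1 step per library, within a tolerance of 0.02 fragments, for 92.9% of 4416 single-transcript loci at 28 somite pairs and 92.4% of 4831 at 38. These were the loci of lower values, under 100 fragments. The step gave a total of 13859394 mapped fragments at 28 somite pairs and 12908611 at 38. These totals assume that the authors' FPKM were scaled to all mapped fragments. Loci with fewer than 10 fragments were nearly always listed at 0, so a 0 can hide up to 9 fragments. No fragment number was given to any of the 2064 genes that share a locus with another gene, but the totals within listed transcripts include their transcripts (6.31% of mapped fragments at 28 somite pairs and 5.16% at 38). Intervals of fragment ratios are exact 95% intervals (Clopper-Pearson), and they cover counting error only.

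Differences are log2(FPKM + 1) at 38 somite pairs minus the same at 28, which understates the difference of low genes. A gene was counted as higher at a stage when its FPKM was at least 1 in one library, the difference was at least 2-fold and the deposited intervals did not overlap. This rule, 33 gene lists and part of the alternatives were chosen before the data were examined, and further alternatives were added after. The files do not pair the gene identifiers with names, and 0 of 21085 identifiers matched the reference table of gene names, which is of the rAnoCar3.1 assembly. The gene lists and the rule for named genes, which took the 12 largest differences each way among genes with a symbol, could therefore not be applied. A planned correction for GC content was not run, since no genome sequence was used here.

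In their place, groups were formed from the annotation by chromosome, transcript length and exon structure after the data were seen. Tandem arrays were runs of at least 8 neighbouring single-exon models, at most 50 kb apart, with lengths within 10% of the array's median. Group medians are given relative to the median of all expressed genes, with a bootstrap interval over genes (1000 draws) and a percentile among 10000 random lists matched on mean expression in 20 bins. Genes are not replicates, so these describe the 2 libraries only. Single loci were picked after their values were seen, as those with at least 100 fragments in one library and at least 10 in both, ordered by fold. A subset with an FPKM of at least 50 in one library was called abundant. At most 2 identifiers are printed for each direction, and other loci are given by position. Positions are 1-based, on AnoCar2.0.

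The steps were tested on simulated data drawn for 10687 genes with 200 genes changed. The rule recovered 55.0% of the genes changed 4-fold and 11.0% of those changed 2-fold, none in the wrong direction, and called 30 unchanged genes. The fragment interval held the true ratio for 97.0% of 197 changed genes. The draws held counting error only, as the interval assumes, so this checks the calculation and not the real libraries. They also took each listed 0 as no fragments, so the 30 calls may be too few. The alternatives covered the pseudocount (0.1, 0.5 and 5 FPKM), the filter on low values, 4 scalings, a length trend (running median over 501 genes) and the rule itself. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.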

Results

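The transcriptomes of 2 whole green anole embryos were compared, one with 28 somite pairs and one with 38. Somites are the paired blocks of mesoderm that form along the body axis, and their number stages the embryo. The embryos were collected 0 to 1 days after laying, and the series sets them beside mouse embryos of 9.5 and 10.5 days. Each stage was 1 library, so no value has a replicate error. The library at 28 somite pairs held 13859394 mapped fragments, of which 7217106 lay in the listed transcripts (52.1%, Wilson 95% interval 52.0 to 52.1). The library at 38 held 12908611, of which 5603606 lay in listed transcripts (43.4%, 43.4 to 43.4).

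Similar numbers of genes were detected at both stages. An FPKM of 1 or more was found for 9850 genes at 28 somite pairs and 9938 at 38. Of the 10783 genes detected in either library, 9005 were detected in both, 845 only at 28 and 933 only at 38. The same 5 genes were the most abundant in both libraries. The first, a single-exon model on contig AAWZ02037236 (9286 to 10821), had 27179 FPKM at 28 somite pairs and 24453 at 38. Another model on that contig (2089 to 2610) had 4982 and 4123 FPKM. A transcript of 135 bases on chromosome 3 (120076424 to 120076936) had 4143 and 5488 FPKM, from only 1926 and 2364 fragments. The first model had 477725 and 402867 fragments, so the rank of the transcript of 135 bases rests on its short length. A locus on chromosome 5 (132534696 to 132541499) had 3419 and 3955 FPKM, and one on chromosome 4 (110131360 to 110145283) had 3130 and 2992. The 100 most abundant genes took 32.4% of the summed FPKM at 28 somite pairs and 33.8% at 38.

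Expression levels of the libraries followed each other closely. Across the 10783 expressed genes, which are not independent replicates, Pearson's r was 0.914 and Spearman's rho was 0.905. The median log2 difference, 38 minus 28 somite pairs, was -0.18, with quartiles at -0.55 and 0.23. Among 4800 genes with at least 100 fragments in both libraries, r was 0.963 and the median difference was -0.22. These shifts depend on the scaling. If FPKM were scaled to all mapped fragments, the smaller share in listed transcripts at 38 (43.4% against 52.1%) by itself lowers values at 38. With values at 38 scaled to an equal sum of FPKM, the median over expressed genes was -0.04.

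Under the rule of 2-fold and separate intervals, 167 genes were higher at 38 somite pairs and 209 were higher at 28. The split depended on the scaling. With values at 38 multiplied by 1.16, which set the median difference near 0 (0.02), 240 genes were higher at 38 and 161 at 28. Those at 38 were 59.9% of calls, against 44.4% as deposited. Most calls rested on a 0, since 117 of the 167 genes were listed at 0 at 28 somite pairs and 112 of the 209 at 0 at 38. Without genes listed at 0 in a library, 50 genes met the rule at 38 and 97 at 28. Calls were mostly of short transcripts. Those under 500 bases were 85 of the 167 calls and 113 of the 209, but only 1107 of the 10783 expressed genes. The 12 largest differences in each direction were all listed at 0 in the other library, in transcripts of 126 to 384 bases for those higher at 28. Those higher at 38 had transcripts of 126 to 903 bases in 11 genes, and the other gene shared a locus, so no length was assigned. Their fragments in the higher library numbered 10 to 67 for those higher at 28 and 10 to 177 for those 11. Set against 10 fragments in the other library, the fold was only 0.95 to 6.23 for those higher at 28. It was 1.07 to 19.1 for those higher at 38, so several of these differences may be small. Simulated counting error gave fewer calls. In 100 simulations of 11292 genes with no difference but an overall one, at most 16 genes were called higher at 38 and 45 higher at 28, against 160 and 200 observed. Most observed calls rested on a 0, and a listed 0 can hide fragments. The simulated numbers may therefore be too low, and they do not bound the calls due to counting error.

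Among abundant loci, the largest difference towards 38 somite pairs was at ENSACAG00000013384 on chromosome 2 (23373004 to 23389612). It had 21.1 FPKM at 28 somite pairs (329 fragments) and 209.1 at 38 (3055 fragments), 9.91-fold higher (95% counting interval 8.84 to 11.1). Next was ENSACAG00000002003 on scaffold GL343260.1 (1472254 to 1479189), with 35.9 and 227.5 FPKM, 6.34-fold higher (5.84 to 6.89). Loci on scaffolds GL343400.1 and GL343286.1 followed, 3.91-fold (3.16 to 4.88) and 3.87-fold (3.12 to 4.83) higher. After them came a locus on chromosome 2 (12969460 to 12974630), 3.64-fold higher (3.36 to 3.96), with 63.3 and 230.5 FPKM. A neighbouring model (12996509 to 13037608) was also higher at 38, from 0.82 to 6.04 FPKM, 7.39-fold (4.88 to 11.6). A locus on scaffold GL343253.1 (499069 to 512404) had 48.2 and 165.2 FPKM, 3.42-fold (3.17 to 3.70). Among lower loci, the largest fold was on scaffold GL343542.1 (48638 to 57820), with 1.29 and 26.0 FPKM from 15.5 and 291.5 fragments. With fragments rounded down to whole numbers it was 20.8-fold higher at 38 (12.4 to 37.6), slightly more than by FPKM. Its fractional fragment numbers can come from reads shared with other loci, which the counting interval does not cover.

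In the other direction, ENSACAG00000015910 on chromosome 4 (121529454 to 121549715) had 86.3 FPKM at 28 somite pairs and 14.4 at 38, 6.0-fold higher at 28 (4.34 to 8.47). ENSACAG00000000369 on chromosome 2 (41747802 to 41757040) had 291.1 and 63.1 FPKM, 4.61-fold higher at 28 (4.0 to 5.34). A locus on chromosome 1 (22860717 to 22864405) had 174.6 and 49.3 FPKM, 3.54-fold higher at 28 (3.03 to 4.15). Of lower loci, one on chromosome 6 (19286963 to 19334220) had 8.42 and 0.63 FPKM, 13.4-fold higher at 28 (9.16 to 20.2). Of 1393 abundant loci, 26 were at least 2-fold higher at 38 and 40 at 28 in FPKM as deposited. Relative to the median of well-covered genes, the numbers were 45 and 20, so the balance depended on the scaling.

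**Figure D1:**
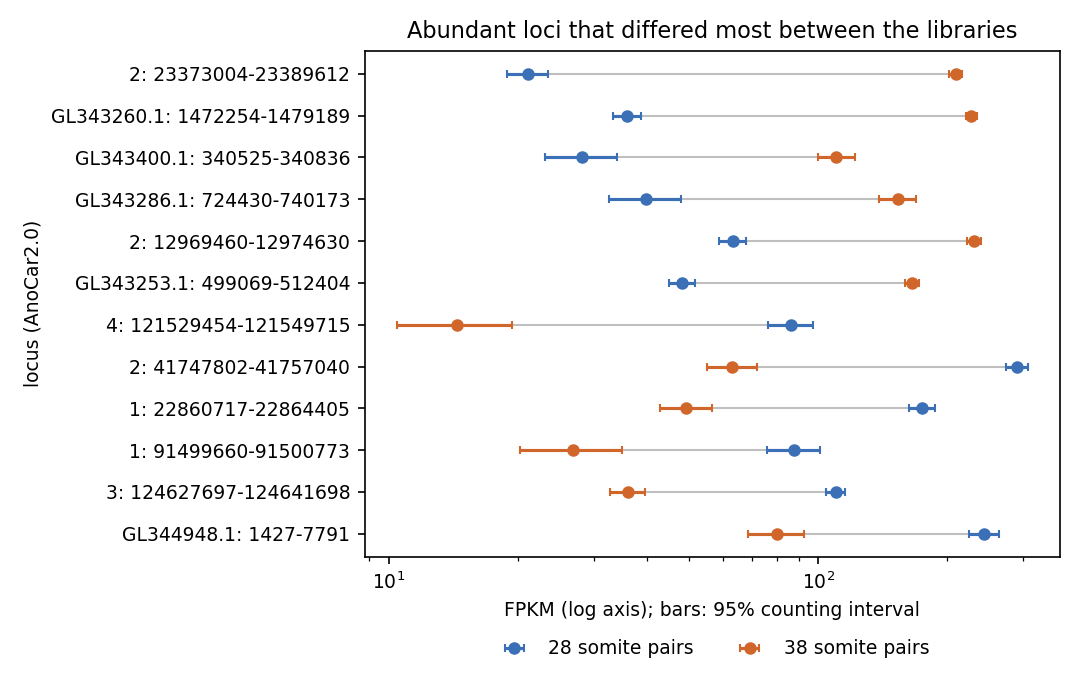
FPKM (log axis) of the 6 abundant loci with the largest fold in each direction, at 28 (blue) and 38 (orange) somite pairs, 1 library each, with 95% counting intervals as bars. The top locus lies at 21.1 FPKM at 28 somite pairs and 209.1 at 38.

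Genes on the small linkage groups of the assembly were lower at 38 somite pairs than other genes. Relative to all expressed genes, the median log2 difference of their 133 expressed genes was -0.22 (bootstrap 95% interval -0.31 to -0.15), below every one of the 10000 matched random lists. Linkage group LGb, which belongs to the X chromosome of this lizard, had a median of -0.28 over 44 genes (-0.39 to -0.15), at percentile 0.31. Of those 44 genes, 11 lay above the overall median. The labels do not give the sex of the embryos. LGf had a median of -0.35 over 38 genes (-0.54 to 0.02, percentile 0.09), and LGc one of -0.17 over 36 genes (-0.25 to 0.00, percentile 7.83). With the length trend removed, the medians were -0.19 over all linkage groups, -0.28 for LGb, -0.28 for LGf and -0.06 for LGc. The random lists were matched on expression only, and GC content was not tested. Chromosome 5 had a median of 0.08 (0.03 to 0.12, 878 genes, percentile 99.99) and chromosome 6 one of 0.06 (0.01 to 0.10, 619 genes, percentile 98.5). Chromosomes 1, 2, 3 and 4 lay between percentiles 5.30 and 89.6.

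Transcript length and exon structure went with the difference. Transcripts under 500 bases had a relative median of 0.13 (0.07 to 0.18, 1107 genes). Those of 4000 bases or more had one of -0.26 (-0.29 to -0.22, 530 genes), and 120 of these 530 genes lay above the overall median. The classes between were in order, at 0.09, 0.04 and -0.08. Single-exon genes outside arrays had a relative median of 0.28 (0.20 to 0.35, 593 genes), against -0.01 (-0.03 to 0.00) for 8781 multi-exon genes. The gap was smaller among genes with at least 100 fragments in both libraries, with a median log2 difference of -0.05 (-0.16 to -0.01) over 157 single-exon genes and -0.23 (-0.24 to -0.21) over 4400 multi-exon genes. Under the rule, 29 single-exon genes outside arrays were higher at 38 and 30 at 28. Of single-exon models outside arrays, 130 were listed above 0 only at 38 somite pairs and 76 only at 28.

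**Figure D2:**
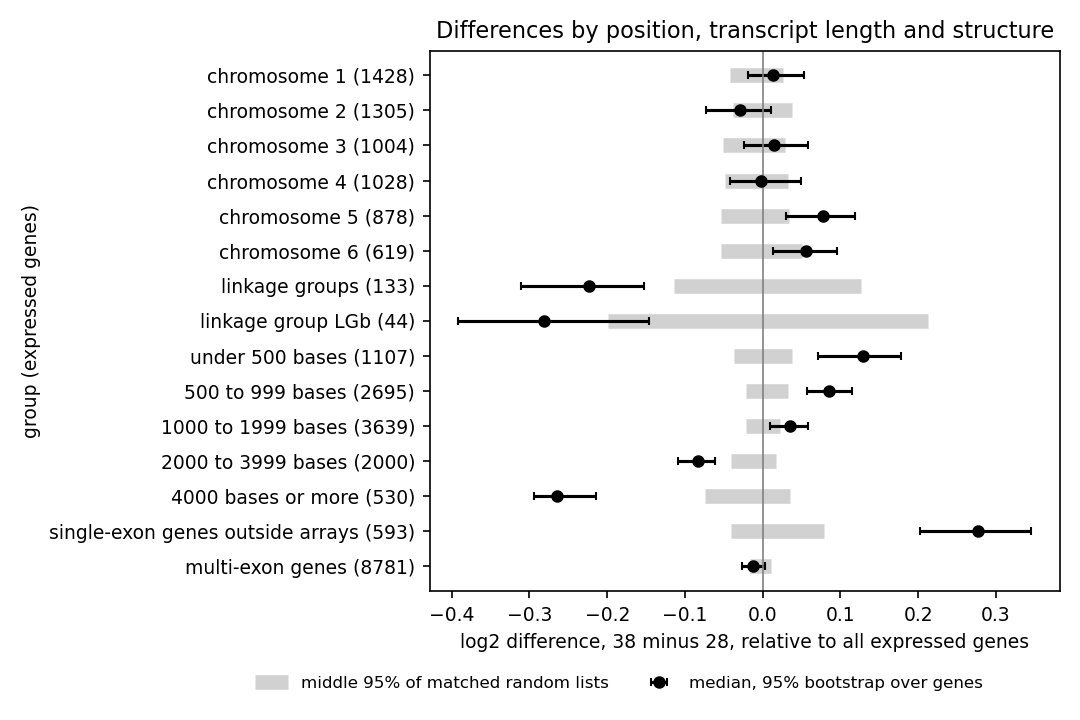
Median log2 difference in FPKM, 38 minus 28 somite pairs, relative to all expressed genes (horizontal axis), for groups of genes by chromosome, transcript length and structure (vertical axis, numbers of expressed genes in brackets). Points are medians, bars 95% bootstrap intervals over genes, and grey bands the middle 95% of random lists matched on expression. The median is 0.13 under 500 bases and -0.26 at 4000 bases or more.

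Of 9 tandem arrays of single-exon models, 6 had listed fragments, and 5 of these had more at 38 somite pairs. On chromosome 4, 3 arrays of models of 2307 to 2628 bases followed each other. The first (76603973 to 76792178, 23 models) had 5008 fragments at 28 somite pairs and 4235 at 38, a ratio per mapped fragment of 0.91 (0.87 to 0.95). This ratio was 1.05 (1.01 to 1.10) with the median difference of genes set near 0 and 1.06 (1.02 to 1.11) with equal upper quartiles. It was 1.00 (0.96 to 1.04) with equal sums, and 1.02 (0.98 to 1.07) with equal sums without the 100 most abundant genes. Its departure from 1 therefore depended on the scaling. The second (76842659 to 77076066, 26 models) had 1797 and 3033 fragments, a ratio of 1.81 (1.71 to 1.92), with 21 models higher at 38 and 5 at 28. The ratio in the second array was 2.0 times that in the first (1.86 to 2.14), whatever the scaling. The last (77222576 to 77415139, 16 models) had 243 and 373 fragments, a ratio of 1.65 (1.40 to 1.95).

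The other 3 arrays held models of 918 to 987 bases with few fragments. On scaffold GL343253.1, the first array (551097 to 786987, 15 models) had 77 and 219 fragments, a ratio of 3.05 (2.35 to 4.01). The next (792258 to 1105037, 17 models) had 172 and 313, a ratio of 1.95 (1.62 to 2.37). An array on chromosome 1 (92320553 to 92505533, 9 models) had 30 and 154 fragments, a ratio of 5.51 (3.71 to 8.45). Counting 9 fragments for each model at 0 at 28 somite pairs lowered these ratios to 1.27 (1.04 to 1.55), 1.38 (1.16 to 1.63) and 1.78 (1.37 to 2.33). Neighbouring copies can share reads, so values of single members are uncertain.

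**Figure D3:**
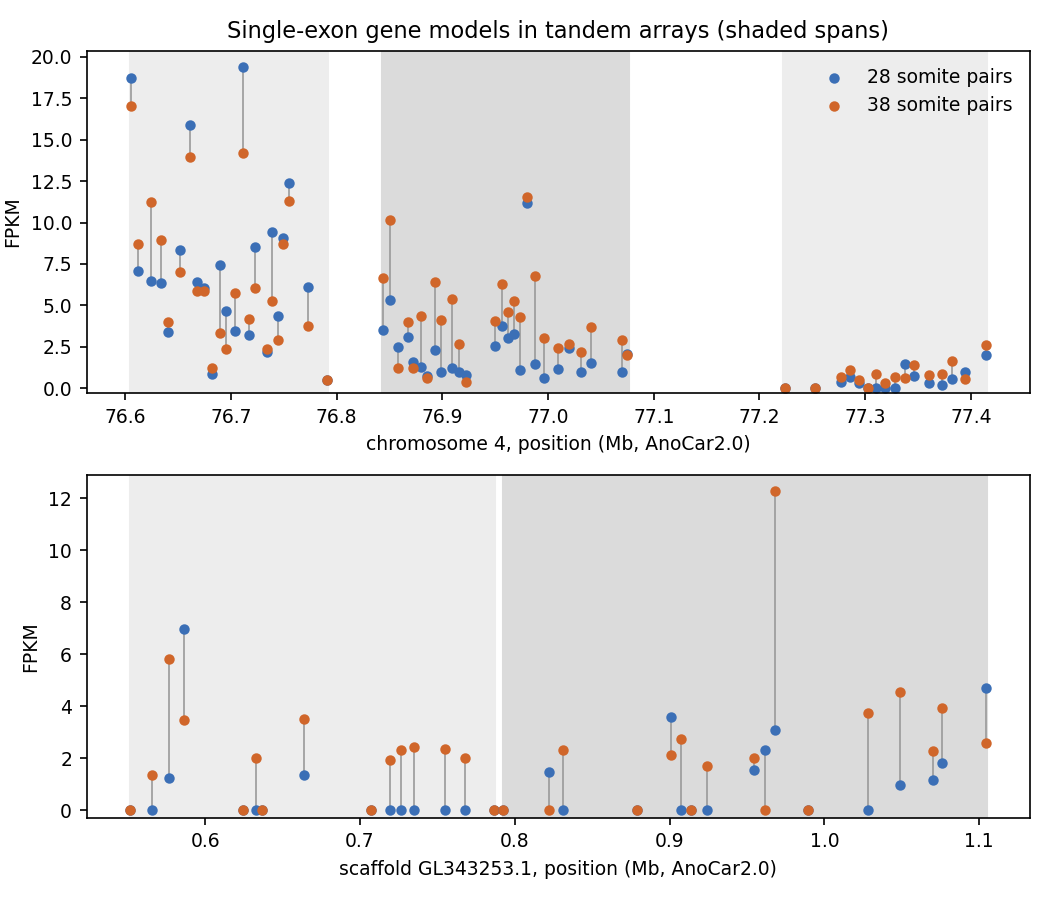
FPKM (vertical axis) of single-exon models in tandem arrays against position in Mb (horizontal axis) on chromosome 4 and scaffold GL343253.1, at 28 (blue) and 38 (orange) somite pairs, 1 library each. Shaded spans are the arrays and grey lines join both values of a model. In the second array on chromosome 4, 21 of 26 models are higher at 38 somite pairs.

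Transcript usage was close between stages for most genes. Of 921 genes with at least 2 annotated transcripts, 241 had an FPKM of at least 5 in both libraries, and their median largest difference in a transcript's share was 3.59 percentage points. The leading transcript differed in 27 genes (11.2%). In 7 genes a share differed by at least 50 points. At a gene on scaffold GL343983.1 (381 to 22781), the share of the transcript of 564 bases was 3.52% at 28 somite pairs and 94.2% at 38, from 121 and 159 fragments. At a gene on scaffold GL343329.1 (1087139 to 1105908), the transcript of 2223 bases had 0.78% and 76.6%, from 844 and 361 fragments. At a gene on chromosome 4 (46997164 to 47085562), transcripts of 6672 and 6675 bases exchanged the lead. The shorter had 65.1% at 28 and 4.24% at 38. Shares are estimates with no interval here, so such exchanges between transcripts of like length are uncertain. No share differed by 50 points among genes with an FPKM of at least 20 in both libraries (0 of 93 genes).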

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

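Fragments outside the listed transcripts were the one signal found in data that no comparison used. They made up 47.9% of mapped fragments at 28 somite pairs and 56.6% at 38. Their positions were not analysed here. There was 1 library per stage, so neither samples far from others nor differences between groups of samples were tested.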

How the results depend on the processing

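No paired analysis was possible because each stage was 1 library. The alternatives of the group medians and array ratios, the fragment-interval rule, and the filters on short transcripts and zeros were chosen after the data were seen. Where no cause is named, the cause was not tested. Of 36 alternative counts of genes, 25 were within 1.5 times the reported count. Genes higher at 38 and at 28 somite pairs numbered 49 and 96 with FPKM of 1 or more in both libraries, and 50 and 97 with FPKM above 0 in both, since most calls rested on a 0. They numbered 925 and 992 by 2-fold alone, and 521 and 597 by 2-fold with a fragment interval apart from 1, over the 9971 genes to which it applied. At 4-fold, 133 were higher at 28. With equal sums (TPM) they numbered 619 and 503, since values grew while the interval rule depends on their scale. Restricting to status OK moved nothing, since every gene had it.

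Pearson's r was 0.781, 0.883 and 0.956 with pseudocounts of 0.1, 0.5 and 5 FPKM, 0.960 with no filter, 0.898 at FPKM of 5 or more in a library and 0.955 at 1 or more in both. Spearman's rho was 0.919 with no filter and 0.937 at FPKM of 1 or more in both. The median log2 difference was -0.20, -0.19 and -0.12 with those pseudocounts, 0 with no filter, where 8856 of 21085 genes were at 0 in both, and -0.22 at FPKM of 5 or more. At an FPKM of 5 or more, 6515 genes were detected at 28 somite pairs and 6271 at 38. The leading transcript differed in 74 genes at a gene FPKM of 1 or more and in 5 at 20 or more. A share differed by 50 points in 32 and 0 genes, and by 30 points in 13.

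Of 383 alternative group medians, 342 stayed within the bootstrap interval. Signs changed in 12, of which 10 stayed within an interval that held 0: 8 for chromosome 4 (0.00062 to 0.025), 1 for chromosome 1 (-0.0043) and 1 for the first array on chromosome 4 (-0.11). The other 2 were transcripts from 2000 and under 4000 bases, at 0.013, and of 4000 bases or more, at 0.0016, after the length trend was removed, which takes the difference away by construction. The median over all linkage groups moved only with no filter, to 0, as did chromosomes 5 and 6. Of the 278 genes listed on linkage groups, 133 were expressed. With no filter, LGb was at -0.31, and LGc and LGf were at 0, each within its bootstrap interval. Transcripts of 4000 bases or more were at -0.19 with a pseudocount of 5 FPKM and -0.31 with no filter. Transcripts under 500 bases and those of 500 to under 1000 bases were at 0.08 and 0.05 with a pseudocount of 5 FPKM. Both were at 0 with no filter, where genes at 0 in both libraries enter with a difference of 0. With filters on expression they stayed at 0.17 and 0.10 (FPKM of 5 or more), 0.15 and 0.08 (1 or more in both), and 0.15 and 0.09 (above 0 in both). All single-exon genes, those in arrays included, had a main median of 0.31 and were at 0.21 with a pseudocount of 5, 0 with no filter, 0.18 at FPKM of 5 or more, 0.21 at 1 or more in both and 0.24 above 0 in both. Those outside arrays, at 0.28 in the main analysis, were at 0.17 with a pseudocount of 5, 0 with no filter, 0.18 at FPKM of 5 or more and 0.18 at 1 or more in both. The second array on chromosome 4 had a median of 1.17 and 0.48 with pseudocounts of 0.1 and 5, and 0.68 with no filter. The first array on GL343253.1 had 4.57, 2.49 and 0.60 with pseudocounts of 0.1, 0.5 and 5, 1.22 with no filter, 1.12 at FPKM of 1 or more in both, 1.12 above 0 in both and 2.69 with equal sums. Such low values depend on the pseudocount. With zeros at 28 at their most, summed ratios were 1.78 on chromosome 1, 1.35 in the last array on chromosome 4, and 1.27 and 1.38 on GL343253.1, all still above 1. Depth limits the short arrays most, since a model with fewer than 10 fragments was listed at 0.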

Other observations

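A few well-covered loci were listed above 0 at one stage only. On chromosome 5 (45328317 to 45345268), 177 fragments lay at 38 somite pairs and the locus was listed at 0 at 28. On scaffold GL343193.1 (6432186 to 6437135), 149 fragments lay at 38 and the locus was at 0 at 28. In the other direction, loci on chromosome 4 (94020666 to 94055427) and chromosome 3 (23613320 to 23666873) had 144 and 155 fragments at 28 somite pairs and were at 0 at 38. These 4 were all the loci with at least 100 fragments in one library and none listed in the other, and they were chosen after their values were seen.

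In the explanations weighed here, the tests on shared reads and on an even background were chosen after the result was seen. The test on an even background was run in 2 forms, and the second was written after the first had given its result. Since a 0 can hide up to 9 fragments, the excess of a model at 38 was bounded from both sides: at the least with zeros at 28 as 9 and zeros at 38 as 0, and at the most the other way round. This bracket was also added after. The test on shared reads was likewise rewritten after an earlier form, on the share of whole values alone.

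The 3 arrays of short models, 41 models together, had more fragments at 38 somite pairs. Reads shared between near-identical copies leave fractional fragment numbers, and 92.9% of 42 values were whole. The difference did not rest on fractional values, since the 39 models with none had a ratio of 1.37 (1.22 to 1.55), zeros at 28 somite pairs counted at their most. Of these 39, 27 were listed at 0 at 28, and a 0 cannot show sharing, so shared reads were not excluded. The minimum of 10 fragments alone does not account for the difference. With zeros at 28 again counted at their most, the ratio over the 41 models was still 1.41 (1.26 to 1.58). An even background of unspliced or genomic fragments at 38 may account for it, and neither form of the test decided. The median excess per model was 6.62 fragments at the least (-8.38 to 9.62), under the limits of 10 and 10.4, and 11.0 at the most (9.0 to 17.6), with both limits inside the interval. Of 27 members at 0 at 28, 16 were listed above 0 at 38, as were 12 of 52 like models outside arrays, but the arrays were picked for being higher. A stage difference also stays open, as untested.

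The second and last arrays of long models on chromosome 4, 42 models together, were higher at 38 as well. Of 75 fragment values, 72.0% were whole (exact 95% interval 60.4 to 81.8). The shares of 92.9% and 92.4% over single-transcript loci came from loci under 100 fragments, so they are not a like comparison. Shared reads were not the whole cause, since the 27 models with no fractional number had a ratio of 1.59 (1.48 to 1.70). Nor was the minimum, with a ratio of 1.75 (1.65 to 1.84) over the 42 models. Both ratios counted zeros at 28 at their most. In its first form, the background test decided nothing, since the limit of 171.5 fragments above the least median excess of 20.7 (10.2 to 43.1) came from 8 models of which only 2 were at 0. In its second form, models listed at 0 among 381 of like length outside arrays gave a limit of 12.5 fragments. The second array's excess of 49.5 (29.7 to 76.8), with no model at 0, was above it. Single-exon models of like length were only 8, so nearly all of the 381 had more than 1 exon. Unspliced or genomic fragments need not count alike in such models, so an even background in the second array was not excluded. The last array, with 6 of 16 models at 0 at 28, stayed open, with an excess of 10.2 at the least (-8.38 to 16.6) and 10.3 at the most (9.0 to 19.9) against 12.3. A stage difference in the second array is a hypothesis, found and tested on the same data.

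Longer transcripts were lower at 38 somite pairs. The effective lengths assigned by Cufflinks do not explain this, since fragment ratios, which do not use them, had a slope of -0.081 log2 units per doubling of length (-0.094 to -0.067, 8729 genes). Counting noise in short genes does not either, since the slope was -0.12 (-0.14 to -0.11) among 4577 genes with at least 100 fragments in both libraries. RNA integrity or priming may have differed between the libraries. With 1 library per stage it cannot be told apart from a stage difference, and the median of -0.26 in transcripts of 4000 bases or more gives no bound. The higher values of single-exon genes and the larger share of fragments outside transcripts at 38 were not tested against it.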
